A study of Mus musculus with 6 samples.

How the data were processed

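RNA from regulatory T (Treg) cells of mouse spleen was sequenced in 6 samples, each a pool of 3 C57Bl/6 mice taken on day 9 of infection with the parasite Toxoplasma gondii. Per the labels, 3 samples came from mice that carry the Foxp3-driven YFP-Cre allele alone (called WT here), and 3 from mice that also carry a floxed Tbx21 gene, so that Cre removes it in Foxp3-expressing cells (called KO here). Tbx21 encodes T-bet. The labels gave no sample from uninfected mice, and how cells were purified and RNA was extracted is not given in the sources used here.

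Per the submitters' processing notes, the authors used bcl2fastq 2.20.0.422, HISAT2 2.1.0, featureCounts 1.6.2 of the Subread package and the mm10 mouse genome. Per the file headers, the authors deposited counts of reads per gene, made by featureCounts over exons grouped by gene name, without strand and without options for multi-mapping or overlapping reads. The deposited counts are whole numbers and were not normalised. Without strand, reads of a gene cannot be told from those of an antisense partner. Without the option for overlapping reads, reads in exons that Foxp3 shares with Ccdc22 and 4930524L23Rik were counted for none of these genes. The Foxp3 count leaves out any such reads. The table pairs each of 23420 gene names with exon positions in mm10, and these positions are the coordinates given here. None of its genes was mitochondrially encoded, so a mitochondrial share could not be computed.

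The table holds each of the 6 libraries in 2 sequencing runs. The deeper run, by total counts, was used, with 1 column per sample. The 6 columns of the other run were not used, and the runs were not summed. The column names show the group but not which labelled replicate a library is. Each name carries a code shared by 1 WT and 1 KO library. Libraries are therefore called by group and by pair A, B or C. Across genes, the deviations of the 2 libraries of a pair from their group means on the log2 CPM scale (prior count of 2) correlated with r of 0.450 in pair A, 0.341 in pair B and 0.641 in pair C. These r values are across genes, which are not independent replicates. Between WT and KO libraries of different codes r ran from -0.490 to 0.134. The highest, WT of pair B with KO of pair A, also exceeded 0.1. By a rule fixed beforehand, all values within pairs above 0.1, the codes were taken to pair the samples. For each gene the deviations of a group's 3 libraries sum to 0, so the r values depend on one another. The rule therefore cannot establish the pairing by itself. No label says what a pair shares. Each library is a pool, so p-values measure the spread between pools.

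Total counts per library were 19796333, 16853034 and 13995700 in WT of pairs A, B and C, and 21207478, 13635347 and 17192293 in KO. At these depths 1 CPM corresponds to about 13.6 to 21.2 counts. Intervals and error terms cover counting error and the spread between pools, and PCR copies could not be removed without molecular identifiers. The counts of any 2 libraries differed by more than sampling noise (chi-square per degree of freedom from 10.5 to 65.8), so each library counted as 1 replicate.

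The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, comparing KO with WT with no covariate. It used filterByExpr (minimum count of 10), TMM factors, a robust fit and Benjamini-Hochberg adjustment over the 12220 genes that passed the filter, with a threshold of 0.05. Because the codes were taken to pair the samples, a second fit added the pair as a block. It is called the paired fit and replaced a block on the labels' replicate number that had been planned. Its source, the code, was known only after the columns were seen. A fold change is KO over WT. CPM values use TMM-scaled library sizes and are given as mean ± SD over 3 libraries. Differences of single genes in CPM were also tested by an exact two-sided permutation test, where 3 libraries against 3 cannot give a p below 0.1. An adjusted p without a named test is from edgeR.

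Gene sets were 31 lists fixed before the data were examined. They cover T helper and Treg programmes, cell division, metabolism, stress, and markers of other cell types and of sex. Of their 640 entries, 608 were in the table, 11 of them under an older symbol. The 30 lists with at least 3 tested genes were compared with all other genes by camera of limma 3.58.1, with its preset correlation of 0.01 and again with an estimated correlation. The fry test was run as well, and called 1 list without the block and 0 with it. Its mixed form, which takes changes in either direction, called 9 lists without the block and 7 with it. With an estimated correlation, 1 list passed without the block, and none of the 30 passed with it, while camera with the preset called 12 of them. Counts within a list are also given adjusted over the list alone.

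Genes named in the text followed a rule fixed beforehand. It took Tbx21 and Foxp3, then the 10 largest changes in each direction among genes past the threshold with a mean of at least 2 CPM and no overlap between groups, leaving out unnamed clones, pseudogenes and receptor segments. It also took the 3 members with the smallest adjusted p of each programme list, the 2 smallest of each other list, and 20 genes of T cell biology. Results for some single genes are not reported. The size part of the rule gave 2 genes in the main test. Applied to the paired fit, it gave 20, and those were chosen after their values were seen, as were other genes so described.

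Both fits were tested on simulated data for 12220 genes, of which 200, from those with a mean of at least 2 CPM, were changed. Counts were drawn with the real library sizes, each gene's real mean in each pair and the dispersions of the paired fit. A pair effect was thus built in, which favours the paired fit. The simulation therefore cannot show whether the real pairs carry such an effect. The fit without the block recovered 14% of genes changed 1.5-fold, 62% of those changed 2-fold, 94% at 4-fold and 98% at 8-fold, with 0 of 12020 unchanged genes called. The paired fit recovered 72%, 94%, 100% and 100%, or 36, 47, 50 and 50 of 50 genes each, with 18 of the 12020 called. Set against all genes it called in this simulation, these 18 were a larger share than its threshold is meant to allow. The share of false calls of the paired fit in the real data was not measured. Alternatives were other normalisation factors, other low-count filters, DESeq2 1.42.0, limma voom, removal of receptor and haemoglobin genes, a non-robust fit, a minimum fold of 1.5, and leaving out each library. Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9 was used for other steps.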

Results

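Treg cells from the spleens of infected mice were profiled by RNA sequencing, with 3 WT and 3 KO pools of 3 mice each, all on day 9 of Toxoplasma gondii infection. Library totals ran from 13635347 to 21207478 counts. Between 14643 and 15313 genes had a count in 5 of the libraries, and 20363 did in the KO library of pair B. The 10 most counted genes took 3.37% to 3.58% of a library. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were counted in every library, at 41.1 to 265 CPM without TMM scaling, and Xist at no more than 0.440.

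The targeted gene was examined first. Tbx21 encodes the transcription factor T-bet and lies on chromosome 11 of mm10, positions 97098007 to 97115331, on the minus strand, with 6 annotated exon intervals. It measured 105, 103 and 45.6 CPM in the WT libraries of pairs A, B and C, and 10.4, 6.07 and 5.77 CPM in the KO libraries. The means were 84.5 ± 33.7 and 7.42 ± 2.61 CPM (SD, n = 3 pools), a log2 fold change of -3.50 (SE 0.42), or 11.3-fold. All 3 KO libraries lay below all 3 WT libraries, with p = 0.1 by the exact permutation test, the smallest it allows. Across all genes, the edgeR test without the pair block gave Tbx21 an adjusted p of 0.146, which did not pass. The paired fit gave a log2 fold change of -3.46 (SE 0.19) and an adjusted p of 2.03e-05. The difference within pairs was -3.32, -4.06 and -2.96 in pairs A, B and C. Without the WT library of pair C, the unpaired adjusted p was 0.00319. Gene-level counts cannot tell whether the remaining KO reads come from exons left after deletion or from cells with an intact gene.

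**Figure D1:**
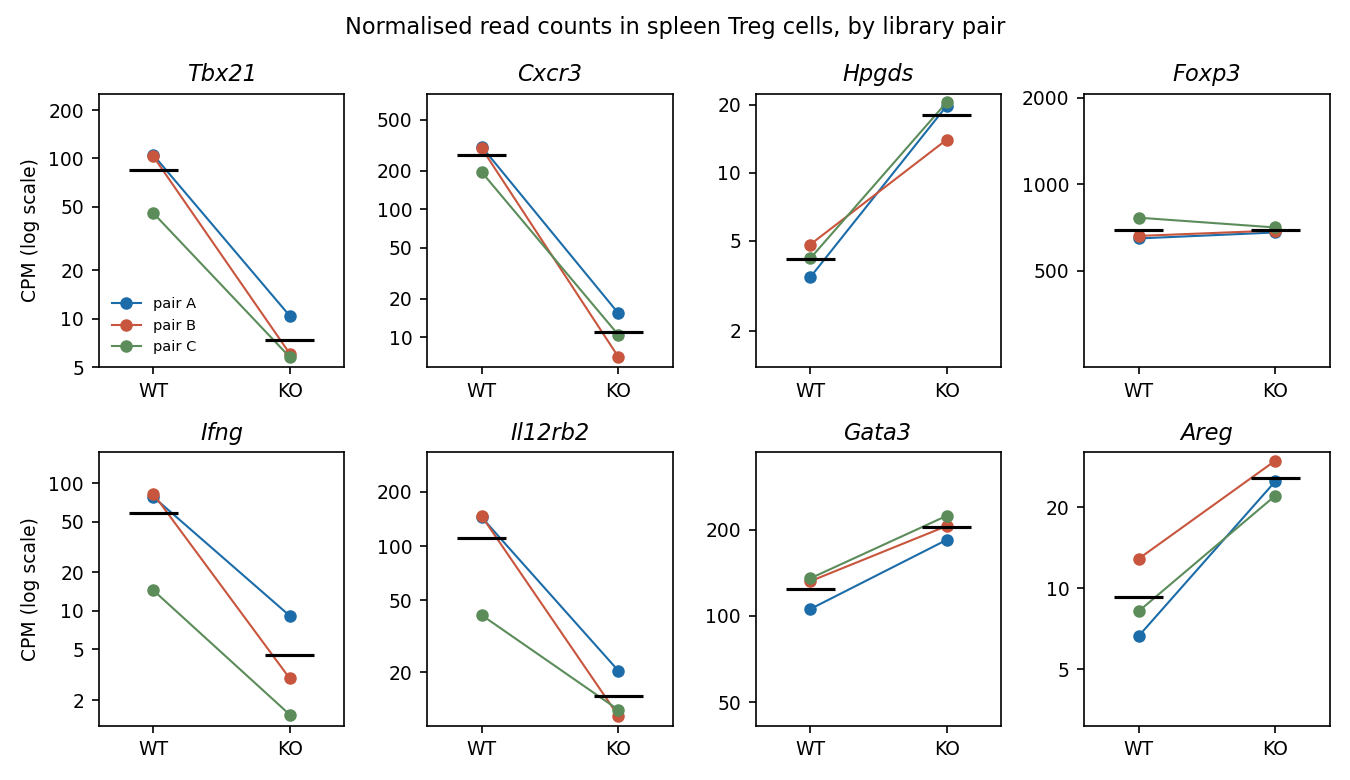
Normalised read counts (CPM, log axis) of 8 genes in WT and KO Treg cells. Each point is 1 library, lines join the 2 libraries of a pair and black bars are group means. Tbx21 fell from a mean of 84.5 to 7.42 CPM and Cxcr3 from 267 to 11.03, Hpgds rose from 4.15 to 18.1, and Foxp3 measured 690.9 and 691.9.

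The comparison of KO with WT asked which part of the Treg transcriptome depends on T-bet during this type 1 helper (Th1) inflammation. The KO cells had far less mRNA for the Th1 homing receptor Cxcr3 and more for Hpgds, the haematopoietic prostaglandin D synthase. Cxcr3 (chromosome X, 101731536 to 101734147) measured 267 ± 62.8 CPM in WT and 11.03 ± 4.23 in KO (n = 3 pools each), a log2 fold change of -4.58 (SE 0.33, adjusted p = 0.0247). Hpgds (chromosome 6, 65117293 to 65144730) measured 4.15 ± 0.683 and 18.1 ± 3.55 CPM, a log2 fold change of 2.13 (SE 0.22, adjusted p = 0.0428). These were the 2 genes past the threshold among 12220 tested without the pair block, 1 higher and 1 lower in KO. At an unadjusted p under 0.05 the same edgeR test had 985 genes, 632 higher and 353 lower, where 611 would be expected by chance. Without the block, DESeq2 called 111 genes and limma voom 1. Cxcr3 had an adjusted p of 0.159 without the WT library of pair A, 0.142 without the WT library of pair B and 0.166 without the KO library of pair C. Hpgds passed with 1 library left out only where that was the WT library of pair C. Its adjusted p otherwise ran from 0.0597 to 0.166.

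Within pairs the difference was broader. The paired fit called 391 genes, 182 higher and 209 lower in KO. Each of the 391 changed in the same direction in all 3 pairs, which follows largely from selecting genes by a test within 3 pairs. Of them, 81 of the higher and 77 of the lower genes changed over 2-fold. Among all 12220 genes, the groups did not overlap in 1745 (14.3%), where chance gives 10%. The common dispersion was 0.0391 without the block and 0.0136 with it. Without pair A the paired fit called 51 genes, without pair B 295 and without pair C 614, of which 48, 204 and 326 were among the 391.

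Among the 10 largest paired losses were genes of the cytotoxic and Th1 lists and genes of neither. Gzmk, which encodes granzyme K, measured 56.6 ± 35.2 CPM in WT and 1.42 ± 1.06 in KO (paired log2 fold change -5.24, SE 0.23). Nkg7, a granule protein gene of cytotoxic cells, measured 154.9 ± 94.8 and 8.10 ± 5.58 CPM (-4.22, SE 0.18). Esm1, Gas7 and Miat also fell, with paired log2 fold changes of -3.57, -3.36 and -3.19. The largest gains were in genes at low levels, among them Capn11 (0.605 to 5.11 CPM), Cd5l (0.634 to 3.88), Slc40a1 (0.973 to 5.37), Col18a1 (0.827 to 4.30), Ubd (0.737 to 3.91), Fn1 (0.914 to 4.28), Npnt (1.30 to 5.89) and Fam69c (0.761 to 3.43). Cd5l and Slc40a1 are expressed by spleen macrophages. The KO library of pair B carried 0.0890 CPM per kb of exon in autosomal genes without a count elsewhere. These genes belong to the 20 largest changes of the paired fit, picked after the values were seen. Of the 20, Cxcr3 and Hpgds passed by edgeR without the block. DESeq2 without the block called 18 of the 20, limma voom 1 and edgeR with no low-count filter 7. Without pair A, the adjusted p of Cd5l was 0.0721, of Slc40a1 0.0737, of Col18a1 0.0737, of Ubd 0.0625, of Fn1 0.245, of Fam69c 0.0796 and of Ccr1 0.194.

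Among 27 tested Th1-associated genes, 9 fell and 0 rose in the paired fit, and 18 did not pass. Besides Cxcr3, Nkg7 and Gzmb they included Ifng, the gene of interferon gamma, with 58.4 ± 38.1 CPM in WT and 4.55 ± 4.05 in KO (paired log2 fold change -3.66, SE 0.31, adjusted p = 0.00303). Il12rb2, a chain of the interleukin 12 receptor, went from 111 ± 59.9 to 14.8 ± 4.92 CPM (-2.75, SE 0.34, adjusted p = 0.0156). Ccl5 went from 97.5 to 13.6 CPM, Ccl4 from 9.23 to 1.46 and Havcr2 from 25.5 to 13.5. Without the block edgeR called 1 of the 27, Cxcr3, over all genes, and adjusted over the list alone 6 fell. DESeq2 without the block called 6 lower, among them Il12rb2, Nkg7 and Ifng, and limma voom 1. In the paired fit adjusted over the list alone, 13 fell and 3 rose. As a list these genes were lower than other genes by camera (adjusted p = 2.59e-11), but the adjusted p = 0.495 with an estimated correlation, and 0.261 with the block. Without pair A 6 genes of the list fell, and Il12rb2 (adjusted p = 0.122) and Ccl5 (0.100) were among those that no longer passed. With no low-count filter the paired adjusted p was 0.268 for Il12rb2 and 0.140 for Ccl5. Without pair C the adjusted p of Ifng was 0.0751. In the WT library of pair C, which had the lowest Tbx21 of the WT libraries, Ifng was also lowest. Over all tested genes this library stood apart from the WT libraries of pairs A and B, and so did the KO library of pair C. On the main axis of variation (43.0% of the variance) the WT libraries of pairs A, B and C lay at -38.4, -21.5 and 26.6. The KO libraries lay at -6.53, 1.93 and 37.9. Both libraries of pair C thus lay highest on this axis, so it does not set the WT library of pair C apart alone. A link between Tbx21 and Ifng levels was not tested.

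Of 17 tested genes of cytotoxic granules and natural killer (NK) receptors, 5 fell and 0 rose in the paired fit. All 5 are granule genes: Gzmk, Nkg7, Ctsw, Gzmb and Prf1. The other 12 did not pass, among them the granzyme gene Gzma, which did not fall. Without TMM scaling, Gzma measured 48.6, 34.1 and 11.4 CPM in WT of pairs A, B and C. In KO it measured 54.6, 41.5 and 29.2 CPM. Gzmb, the granzyme B gene, measured 720 ± 427 CPM in WT and 330.1 ± 203 in KO (paired log2 fold change -1.11, SE 0.13, adjusted p = 0.00402), and Ctsw measured 38.1 ± 11.3 and 9.64 ± 2.35 (-1.97, SE 0.15). The perforin gene Prf1 went from 27.8 to 14.5 CPM, with an adjusted p of 0.177 without pair A and 0.086 without pair B. Without the block edgeR called 0 of the 17 (6 at an unadjusted p under 0.05), and adjusted over the list alone 4 fell. DESeq2 without the block called 4 lower (Gzmk, Nkg7, Ctsw and Prf1) and limma voom 0. The list was lower by camera (adjusted p = 1.17e-05), with an adjusted p = 0.495 with an estimated correlation. The list member Klrg1 measured 74.5 and 79.6 CPM. Eomes, a T-box gene outside this list, measured 4.39 CPM in both groups.

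**Figure D2:**
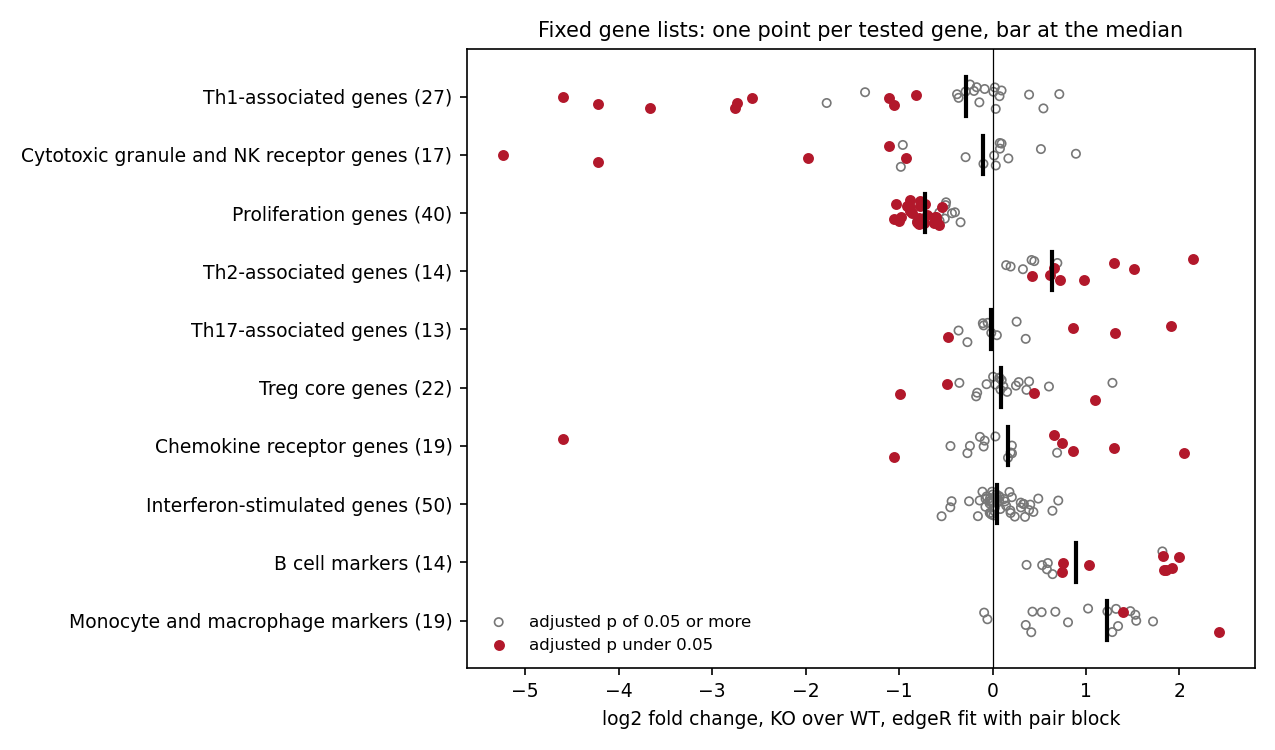
Paired log2 fold change (KO over WT) of every tested gene in 10 lists fixed before the data were examined, with the number tested in parentheses. Filled points passed the paired test, open points did not, and black bars are medians. All 40 proliferation genes lie below 0, all 14 Th2-associated genes lie above 0, and the Th1 list holds 9 filled points, all below 0.

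Genes linked to type 2 helper (Th2) cells were higher in KO. In the paired fit 8 of 14 rose and 0 fell. The Th2 master regulator Gata3 went from 124 ± 16.2 to 205 ± 19.7 CPM (log2 fold change 0.72, SE 0.09, adjusted p = 0.00490), the growth factor gene Areg from 9.25 ± 3.25 to 25.6 ± 3.91 (1.51, SE 0.16) and the interleukin 33 receptor gene Il1rl1 from 122 ± 36.6 to 231 ± 12.6 (0.97, adjusted p = 0.00823). Pparg rose from 0.585 to 2.61 CPM, and the other 4 were Ccr4, Ccr8, Epas1 and Il4ra. Without the block edgeR called 0 of the 14 over all genes (8 at an unadjusted p under 0.05) and 8 rose adjusted over the list alone. DESeq2 without the block called 7 higher, among them Gata3, Areg, Pparg and Ccr8, and limma voom 0. The paired DESeq2 test did not call Pparg (0.0737). The list was higher by camera (adjusted p = 1.99e-16), which held with an estimated correlation (adjusted p = 0.0471) but not in the paired fit (adjusted p = 0.261 with an estimated correlation). Without pair A 4 of the 14 rose, and Pparg (adjusted p = 0.101) and Ccr8 (0.220) did not pass. The cytokine gene Il4 measured 0.790 ± 0.624 and 0.940 ± 0.140 CPM.

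Of 13 genes linked to Th17 cells, 3 rose, among them the interleukin 1 receptor gene Il1r1 and the chemokine receptor gene Ccr6, and Il6st fell in the paired fit. Without pair A that fit called 0 genes of the list, without pair B 1 rose and 0 fell, and without pair C 2 rose and 1 fell. Il1r1 went from 1.89 to 4.67 CPM, with an adjusted p of 0.178 without pair A, 0.100 without pair C and 0.184 by paired DESeq2. Il6st went from 472 to 339 CPM, with an adjusted p of 0.0737 without pair A and 0.161 without pair B. Without the block edgeR called 0 of the 13 (5 at an unadjusted p under 0.05), DESeq2 1 and limma voom 0. Adjusted over the list alone 4 rose and 1 fell. The list's median was -0.05 and its mean 0.25, and camera, which gave the direction of the mean, did not pass (adjusted p = 0.108). It passed without the KO library of pair C (0.0125), and with the block without pair C (0.0133). Il17a had no counts in 5 libraries and 2 in the KO library of pair B.

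The Treg identity genes did not move as a group. Foxp3 measured 690.9 ± 64.3 CPM in WT and 691.9 ± 14.1 in KO, with a log2 fold change of 0.00 (SE 0.10) and p = 1.0 by the exact permutation test. Its sign differed between normalisations. Of 22 core Treg genes, Penk and Capg rose and Il2rb and Entpd1 fell in the paired fit, and adjusted over the list alone 7 rose and 2 fell. Without the block edgeR called 0 of the 22 (7 at an unadjusted p under 0.05), limma voom 0 and DESeq2 3 (Il2rb, Penk and Itgae). Il2rb, a chain of the interleukin 2 receptor, measured 1680 ± 94.0 CPM in WT and 845 ± 74.7 in KO (log2 fold change -0.99, SE 0.11), with an adjusted p of 0.0559 without the block and 0.00239 with it. Without the block it was the 1 gene of the list past the threshold adjusted over the list alone, and it passed over all genes with median-of-ratios factors (0.0480), a non-robust fit (0.0456), no low-count filter (0.00400) and DESeq2 (3.46e-18). Penk went from 42.0 to 87.6 CPM. The paired adjusted p of Entpd1 was 0.153 without pair A, 0.253 without pair B, 0.0573 with upper-quartile factors and 0.0576 with library totals only. Ikzf2 measured 954 and 996 CPM, Ctla4 1414 and 1212, and Il2ra 467 and 611, none past either edgeR test. Itgae measured 58.3 and 138 CPM. It did not pass either edgeR test, but passed by DESeq2 without the block (0.00122), and with the block by limma voom (0.0235) and a non-robust fit (0.0276). Camera did not call the list (adjusted p = 0.233, and 0.0936 with the block). Without pair A the paired list test gave 0.0200, and without pair C 0.0138. The mixed fry test, which takes changes in either direction, called the list without the block (adjusted p = 0.00996) but not with it (0.0561).

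Of 19 suppressive effector genes, 4 rose (Areg, Ebi3, Fgl2 and Icosl) and 3 fell (Gzmb, Prf1 and Entpd1) in the paired fit. Without pair A 2 rose and 1 fell, without pair B 3 and 1, and without pair C 3 and 5. Ebi3, a subunit of interleukin 35, went from 32.2 ± 4.29 to 58.2 ± 5.38 CPM (log2 fold change 0.86, SE 0.11), while Il10 measured 61.5 ± 28.2 and 45.0 ± 13.4 and did not pass. Of the 19, edgeR without the block called 0 (8 at an unadjusted p under 0.05), and adjusted over the list alone 5 rose and 2 fell. DESeq2 without the block called 4 (Areg, Ebi3, Fgl2 and Prf1) and limma voom 0. Paired DESeq2 did not call Icosl. Camera did not call the list (adjusted p = 0.233), except without the WT library of pair A (0.0256). Of 25 genes of effector or activated Treg cells, 4 rose (Tnfrsf9, Cd44, Ccr8 and Cd83) and 2 fell, among them Gzmb, in the paired fit. Without pair A 0 rose and 1 fell in that fit, without pair B 2 and 2, and without pair C 5 and 3. The edgeR test without the block called 0 of the 25 (7 at an unadjusted p under 0.05), limma voom 0 and DESeq2 4. That list was higher by camera without the block (adjusted p = 0.0320), with an adjusted p = 0.762 with an estimated correlation, and was not called with the block (0.308), with limma voom (0.0922) or with no low-count filter (0.131). Without the KO library of pair A its adjusted p was 0.101, without the KO library of pair B 0.232 and without the WT library of pair C 0.943. Cd44 went from 76.8 to 118 CPM, with an adjusted p of 0.122 without pair A and 0.108 without pair B. Among 19 chemokine receptor genes, Gpr183, Ccr1, Ccr4, Ccr8 and Ccr6 rose and 2 fell in the paired fit, among them Cxcr3. Without the block edgeR and limma voom each called Cxcr3 alone, and DESeq2 called 4 higher and 1 lower. Without pair A 2 rose and 1 fell in the paired fit, without pair B 4 and 2, and without pair C 4 and 3. Gpr183 went from 102 to 169 CPM and Ccr1 from 1.80 to 8.06. Markers of B cells and macrophages were also higher in KO, as given below. Which cells gave rise to the gains in the lists of this paragraph was not tested. Of 19 co-inhibitory receptor genes, Entpd1 and Havcr2 fell in the paired fit. Without the block edgeR, DESeq2 and limma voom each called 0 of them. The paired fit called 0 without pair A, 1 higher and 0 lower without pair B, and 0 higher and 3 lower without pair C. Camera called neither of the last 2 lists (adjusted p = 0.705 and 0.990). For chemokine receptors it gave the direction up without the block and down with it, where the median was 0.17.

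Cell division genes were lower in KO within each pair. All 40 proliferation genes had a negative fold change, 37 of them in all 3 pairs, and 28 fell in the paired fit, where adjusted over the list alone 40 fell. Mki67 measured 480 ± 271 CPM in WT and 267 ± 146 in KO (paired log2 fold change -0.81, SE 0.10, adjusted p = 0.00472) and Ccnb2 52.9 ± 28.9 and 25.5 ± 13.3 (-1.05, SE 0.12). The list's median log2 difference was -0.84, -0.77 and -0.40 in pairs A, B and C. The SD of Mki67 between WT pools exceeded the difference between its group means. Without the block edgeR, DESeq2 and limma voom each called 0 of the 40 over all genes, edgeR had 1 at an unadjusted p under 0.05, and adjusted over the list alone 0 passed. Camera called the list (adjusted p = 3.60e-06, and 2.06e-47 with the block), but the adjusted p = 0.762 with an estimated correlation, and 0.276 with the block. It was 0.0600 by camera without the KO library of pair C. Without pair A 4 proliferation genes fell in the paired fit, without pair B 13 and without pair C 38.

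Metabolic and stress lists showed few gene-level changes. Camera called oxidative phosphorylation genes lower (30 tested, median log2 fold change -0.22, adjusted p = 1.19e-05, and 0.762 with an estimated correlation) and glycolysis genes lower (20 tested, median -0.22, adjusted p = 0.00938, and 0.762 with an estimated correlation). The glycolysis call had an adjusted p of 0.0568 without the WT library of pair A and 0.239 without the WT library of pair B, and with the block 0.143 without pair B. In these lists the paired fit called Hk2 alone, from 27.8 to 15.7 CPM. Cholesterol synthesis genes (21 tested) were called lower by camera with the block (adjusted p = 0.0333, and 0.378 with an estimated correlation) but not without it (0.0924), and with the block their adjusted p was 0.0791 without pair C. Without the block they were called lower with no low-count filter (0.00291), without the WT library of pair C (0.00243) and without the KO library of pair B (0.00139). Camera did not call the 20 apoptosis genes (adjusted p = 0.136), except lower with no low-count filter (0.00291, and 0.00148 with the block) and with the block without pair C (0.0479). With no filter the median log2 fold change of all genes was 0.155 over 20790 genes, against -0.00054 over 12220 with the filter. Camera compares a list with all other genes, so a list called lower with no filter need not have fallen itself. Neither edgeR test called a gene among 50 interferon-stimulated, 22 unfolded protein response, 23 immediate-early and handling-stress, 17 follicular helper and 19 resting Treg genes, and camera called none of these 5 lists in the test without the block or the paired fit with all libraries and the usual filter. At an unadjusted p under 0.05 the test without the block had 6, 1, 3, 2 and 1 of them. DESeq2 called Dusp2, an immediate-early gene, without the block (0.0307) and with it (0.00978). With the block it also called Cxcr5 (0.0305) and Angptl2 (0.0333) of the follicular helper list and Serpina3g of the interferon-stimulated list. With no low-count filter the paired edgeR fit called Dusp2 (0.0155), Cxcr5 (0.0198) and Txk (0.0480). Limma voom called none of these genes in either fit. Leaving out pair B, the paired fit called 2 interferon-stimulated genes lower and 2 follicular helper genes higher. Leaving out pair C, it called 7 interferon-stimulated genes higher and 1 lower, 2 follicular helper genes lower, and 1 immediate-early gene each way. The smallest of their adjusted p values without the block were 0.0694 for resting Treg genes and 0.0852 for interferon-stimulated genes. Resting Treg genes were called lower without the WT library of pair A (6.06e-05), the WT library of pair B (0.00404) or the KO library of pair C (5.86e-04), and with the block without pair A (0.0200) or B (0.0378). They were also called lower with no low-count filter (0.00103, and 0.00328 with the block), as were unfolded protein response genes (0.0250 and 0.0235), which also passed without the WT library of pair C (0.00192). Interferon-stimulated genes were called higher after background subtraction (0.04996), without the WT library of pair C (8.43e-04), without the KO library of pair C (3.66e-04), and with the block without pair C (8.99e-08). Follicular helper genes were called higher with the block without pair B (0.0192).

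Markers of some other cell types were also higher in KO. Of 14 B cell markers, 8 rose in the paired fit, among them Ms4a1 (1.11 to 4.18 CPM), Spib (0.985 to 3.50) and Cd74 (153 to 249). Without the block edgeR called 0 over all genes (9 at an unadjusted p under 0.05) and 8 rose adjusted over the list alone. DESeq2 without the block called 3, among them Ms4a1 and Spib, and limma voom 0. The paired DESeq2 test called 4, without Spib (0.0779). The list was higher by camera (adjusted p = 2.39e-15, and 0.335 with an estimated correlation). Of 19 macrophage markers, Slc40a1 and Csf1r rose in the paired fit, and 13 were higher in all 3 pairs (camera adjusted p = 4.44e-10, and 0.335 with an estimated correlation). The edgeR test without the block called 0 of the 19 (9 at an unadjusted p under 0.05), limma voom 0 and DESeq2 1. Adjusted over the list alone, 13 of the 19 rose in the paired fit and 1 without the block. Camera also called plasma cell markers (6 tested, adjusted p = 0.0182), of which Mzb1 rose in the paired fit, and dendritic cell markers (9 tested, 0.0403), of which Wdfy4 rose in the paired fit, each with an adjusted p = 0.762 with an estimated correlation. The plasma cell call had an adjusted p of 0.113 and 0.234 without the WT libraries of pairs B and C and 0.370 without the KO library of pair A. The dendritic cell call had 0.0541 with library totals only, 0.0552 with limma voom, 0.287 without the WT library of pair C, 0.370 without the KO library of pair A, and 0.112 with the block without pair A. Erythroid markers (9 tested) passed with the block (4.63e-06, and 0.261 with an estimated correlation), with Slc4a1 and Hemgn higher, but not without it (0.0673). Without the block they passed with a non-robust fit (0.0370) and without the WT library of pair A (2.64e-06), the KO library of pair B (2.24e-05) or the KO library of pair C (0.00140). Without pair A the adjusted p of Hemgn was 0.309 and that of Wdfy4 0.140. Paired DESeq2 did not call Hemgn (0.226) or Mzb1. In the paired fit adjusted over each list alone, 10 of 14 B cell, 4 of 6 plasma cell and 6 of 9 erythroid markers rose. Without the block 0 plasma cell and 0 erythroid markers did. Cd8a went from 1.37 ± 0.126 to 5.62 ± 4.88 CPM, with a paired adjusted p of 0.0468 that was 0.236 without pair A, 0.188 without pair B, 0.0826 by DESeq2 and 0.0519 with a non-robust fit. Without pair A none of the B cell markers passed. Conventional CD4 T cell markers (10 tested), NK cell markers (6), neutrophil markers (6), platelet markers (4), CD8 markers (4) and sex-linked genes (4) were not called by camera in either fit with all libraries and the usual filter. Neutrophil markers were called higher with no low-count filter (0.0344, and 0.00231 with the block), without the KO library of pair B (5.71e-05) or C (0.00711), and with the block without pair B (0.00110) or C (0.0170). CD8 markers passed without the KO library of pair C (0.0194), and conventional CD4 markers were lower with the block without pair A (0.0271). For NK cell markers the median was 0.26 and the mean 0.06, while camera gave the direction down. Ifng of the conventional CD4 list and Prf1 of the NK list fell in the paired fit.

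A planned comparison asked whether called genes lay close to Tbx21, within 5 Mb on either side. Without the block, 0 of the 2 called genes did. In the paired fit 8 of 145 genes in this window were called, or 5.52%, against 3.16% elsewhere (Fisher's exact test, two-sided, p = 0.144, odds ratio 1.79, 95% interval 0.751 to 3.66), which did not differ detectably. Within 15 Mb, a width chosen after the result was seen, 27 of 322 genes were called, or 8.39%, against 3.05% (p = 4.57e-06 by the same exact test). They changed in both directions, with Dhx40 (-1.74 on the paired log2 scale), Bzrap1 (-1.91) and Ypel2 (-1.24) lower and Pctp (1.43) and Vmp1 (0.77) higher.

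**Figure D3:**
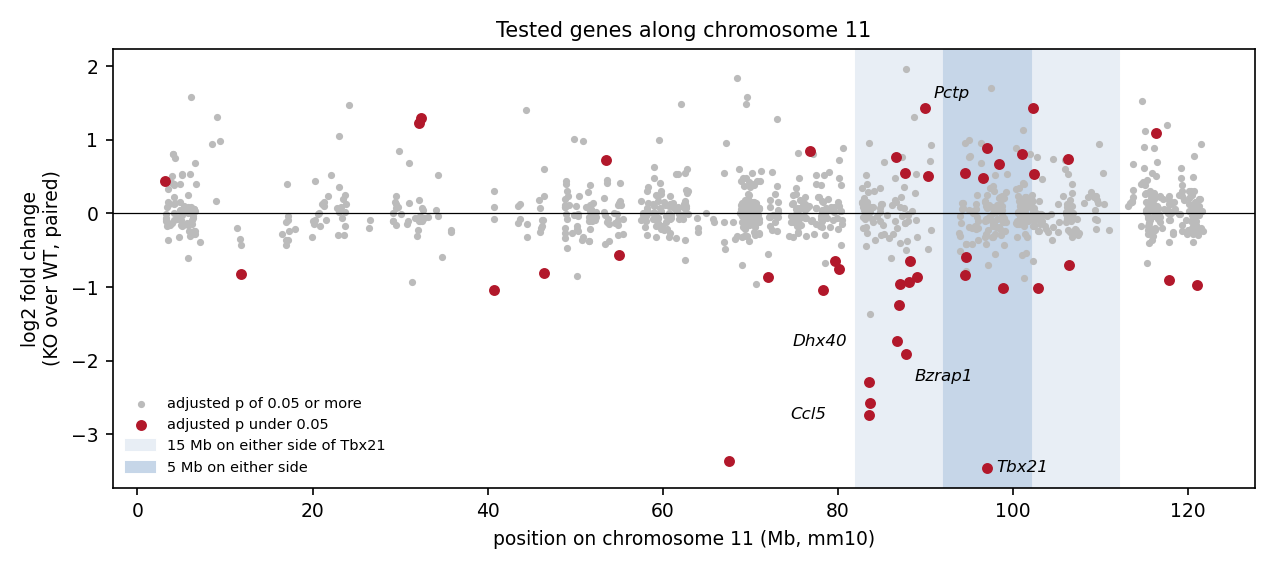
Paired log2 fold change (KO over WT) of each tested gene against its position on chromosome 11 in Mb (mm10). Red points passed the paired test, and shading marks 5 and 15 Mb on either side of Tbx21. Within 15 Mb, 27 of 322 genes other than Tbx21 were called, in both directions.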

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

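The alternatives with the pair block, the background subtraction and the 15 Mb window were chosen after the data were seen, and the others were chosen before the data were examined. No paired analysis by the labels' replicate number was possible because the columns carry none, and the code shared in the column headers served as the block.

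The number of different genes (2 in the main test, 1 higher and 1 lower) depended most on the design: 391 with the replicate block (182 higher, 209 lower), 111 with DESeq2 (56 and 55), 34 with no low-count filter (22 and 12), 4 with a non-robust fit (3 lower), 2 lower with median-of-ratios factors, and 1 with limma voom or with a minimum fold of 1.5 (0 higher in each). The median log2 fold change of all genes was 0.16 with no filter (20790 genes) and with DESeq2 (20777 genes). In the main test it was -0.00054 over 12220 genes, so these medians cover different sets of genes. With 1 library left out the number ran from 0 to 30 (higher 0 to 4, lower 0 to 26). It was 0 without the WT library of pair A or B or the KO library of pair C, 1 without the KO library of pair A or B, and 30 without the WT library of pair C. In the paired fit the number was 598 with no filter (331 lower), 107 were higher and 209 lower with DESeq2, 208 and 172 with totals only, 189 and 171 with upper-quartile factors, 163 and 212 with median-of-ratios factors, and leaving out 1 pair gave 51 to 614 (higher 18 to 262, lower 33 to 352). Subtracting background left 2 genes without the block and 366 with it, 365 of them among the 391.

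Tbx21 kept its direction in every fit. It passed at -3.52 with DESeq2, -3.50 with the non-robust fit (adjusted p = 0.0456) and -3.46 with the replicate block, and ran from -3.85 to -3.32 with 1 library left out (adjusted p 0.00319 to 0.669). Among called genes, the share within 5 Mb of Tbx21 was 1.82% with DESeq2 and 2.05% with the block, from 0 in the main test. Both lay above the share among genes not called, but neither differed detectably from it (Fisher's exact test, p = 0.393 and 0.144). The cause of these shifts was not tested.

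Values near 0 changed sign. Foxp3 was -0.0156 with DESeq2, -0.0051 with median-of-ratios factors and -0.0153 with no filter (-0.0504 to 0.0818 with 1 library left out), and in the paired fit -0.0116, -0.00091 and -0.0117 (-0.0334 to 0.0617). Eomes was -0.0118, -0.0031 and -0.0125 in the same 3 settings, -0.00060 with the block and -0.0292 after background subtraction (-0.0770 to 0.0788), and in the paired fit 0.0337 with upper-quartile factors, 0.0398 with totals only and 0.0043 with voom (-0.0530 to 0.0692). List directions turned at these adjusted p values: co-inhibitory receptors 0.989 (upper-quartile), 0.997 (totals only), 0.350 (no filter), 0.882 (block) and 0.914 (paired voom); chemokine receptors 0.772 (no filter), 0.882 (block) and 0.484 (paired voom); NK markers 0.882 (block) and 0.828 (paired, no filter).

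With 1 library left out, signs also turned for lists whose adjusted p ran from 0.0256 to 0.660 (suppressive effector), 1.67e-04 to 0.943 (effector), 6.06e-05 to 0.463 (resting), 0.0647 to 0.965 (chemokine receptors), 3.66e-04 to 0.965 (interferon-stimulated), 0.325 to 0.992 (co-inhibitory), 0.00192 to 0.854 (unfolded protein response), 5.71e-05 to 0.375 (neutrophil), 2.64e-06 to 0.836 (erythroid), 0.303 to 0.992 (NK) and 0.151 to 0.846 (platelet). With 1 pair left out the ranges were 0.294 to 0.562 (suppressive effector), 0.484 to 0.764 (chemokine receptors), 8.99e-08 to 0.885 (interferon-stimulated), 0.405 to 0.877 (co-inhibitory), 0.00110 to 0.302 (neutrophil), 0.294 to 0.8999 (NK), 0.0690 to 0.479 (CD8) and 0.112 to 0.824 (platelet). Log2 fold changes that turned were Klf1 (-0.14 to 3.20), Hemgn (-0.0211 to 3.57), Gzma (-0.0276 to 0.83), Klrg1 (-0.13 to 0.35), Il4 (-0.12 to 1.12), Bcl6 (-0.0047 to 0.29), Ctla4 (-0.39 to 0.10) and Ikzf2 (-0.0822 to 0.16), and with a pair left out Tubb1 (-0.20 to 0.96), Il4 (-0.13 to 1.14), Ctla4 (-0.33 to 0.10) and Ikzf2 (-0.11 to 0.19).

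Outside the settings that leave out a library, 278 list values without the block kept their direction and side of the threshold, 7 turned, 9 gained a call and 5 lost one. In the paired fit these were 232, 3, 4 and 0. For gene-level values they were 881, 10, 68 and 1 without the block, and 834, 6, 20 and 12 in the paired fit.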

Other observations

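All tests in this part on chromosome position, background and other cell types were chosen after the results were seen, and the planned 5 Mb window is used here with the paired calls, which were not planned.

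Several genes outside the fixed lists differed in the paired fit and were picked after their values were seen. The semaphorin genes Sema7a (27.9 to 7.80 CPM) and Sema6d (4.32 to 0.786) fell, as did the receptor gene Slamf7 (37.6 to 7.45), the cell cycle inhibitor gene Cdkn1a (29.6 to 9.49), C1qtnf6 (59.1 to 13.2) and the annexin gene Anxa2 (175 to 68.7). Among genes that rose were Axl (53.4 to 78.6), Cd86 (23.1 to 42.6), Ltb4r1 (6.02 to 11.8), the inflammasome gene Naip5 (48.3 to 92.7) and Nid2 (11.7 to 25.3). Of these 11, edgeR without the block called 0 (10 at an unadjusted p under 0.05), limma voom 0 and DESeq2 6. Paired DESeq2 called 10, without Ltb4r1.

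The KO library of pair B had a count in 20363 genes, against 15313 at most in the other 5. Its total, 13635347, was the lowest of the 6, which argues against depth. Among 5761 autosomal genes without a count elsewhere, 61.1% had one here, at 1.21 counts per kb of exon, including 739 counts in 1032 olfactory receptor genes. Reads from genomic DNA are a candidate explanation, and in male mice would give X-linked genes 0.5 times the density of autosomal ones; the ratio was 0.229 (95% interval 0.201 to 0.259), below that value and far below 1, so the source stays open. The expected background summed to 0.583% of the library.

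The B cell and macrophage lists were called higher in KO by camera, though not with an estimated correlation. Of the 14 B cell markers, 10 were higher in all 3 pairs. Among these are the 8 that passed the paired test, where every called gene changed alike in all 3 pairs, so this count cannot decide against 1 pair alone. The list's median log2 difference was 0.89, 0.85 and 1.49 in pairs A, B and C, but without pair A 0 of the 14 passed. After background was subtracted 7 of the 14 passed the paired test, against 8 before, which argues against that background. RNA of whole B cells or macrophages may add such transcripts, yet the abundant class II genes H2-Aa, H2-Ab1 and H2-Eb1 had a median log2 difference of 0.72 and 1.53 in pairs A and C and -0.36 in pair B, while the other 11 markers had 1.23, 1.46 and 1.38. How the cells were purified is not given in the sources used here, so carried-over cells and expression in KO Treg cells cannot be told apart, and the effect of genotype was not tested separately.

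Called genes lay more densely around Tbx21 in the paired fit. A chromosome segment of another strain, carried along with the targeted allele, may contribute: p was 0.144 within 5 Mb, and 0.0181 without list genes and genes that followed the proliferation list (r over 0.9), a choice made after the result was seen (Fisher's exact test). The p of 4.57e-06 within 15 Mb describes a width chosen after the cluster was seen and is not evidence for it. Without the same genes, 20 called genes remained within 15 Mb, or 6.92% of the genes there against 1.93% elsewhere. The odds ratio was 3.77 (p = 2.17e-06 by the same exact test), against 2.91 with all genes. Both the width and the removal were chosen after the result was seen. These values therefore do not decide whether those genes are the whole cause. Of 289 other windows of 30 Mb, 4 had as large a share of called genes, up to 10.7% against 8.39%. These 4 overlap and form 1 region of chromosome 13 (75 to 120 Mb), which holds the called genes Gzmk, Esm1 and Il6st. No sequence variants were examined, so the source stays open.

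Splits of the samples were too few for a share under 0.05. Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 2 genes (1 higher, 1 lower), and the highest other 0 in each case, so 1 split reached each result. For gene lists past the threshold the real value was 11 and the highest other 21, with 4 splits at 11 or more; that highest split set the WT libraries of pairs A and B and the KO library of pair A against the rest. Of the 4 splits that part every pair, the real one gave 391 genes in the paired fit (182 higher, 209 lower), and the highest other 0, again 1 split each. The other 3 each exchange the 2 libraries of 1 pair.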
